A study of Arabidopsis thaliana with 11 samples.

How the data were processed

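DNA methylation was measured by whole-genome bisulfite sequencing (MethylC-seq), which converts unmethylated cytosines and reads methylated ones as cytosine. Per the labels, the DNA came from immature flower buds (inflorescence stages 1 to 12) of Arabidopsis thaliana, accession Columbia, and the libraries were read as single ends of 150 bp. The series lists 11 samples, of which 3 are wild type and the others carry 8 mutant genotypes. The methylation table recorded for wild-type replicate 1 was analysed. Its name says wild type without a replicate number. The other 2 wild-type replicates and all mutants were not analysed here, so genotypes were not compared.

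The deposited table gives, for each cytosine, the count of methylated reads and the count of all reads, together with the strand and the sequence context. It also carries the authors' call of the cytosine as methylated or not. Per the submitters' processing notes the genome build was TAIR10. The aligner, the caller, the handling of clonal reads and whether libraries were pooled are not given in the sources used here. The table lists 41481405 cytosines on the 5 nuclear chromosomes, covered by 504819766 reads over cytosines. Mean depth was 12.2 and median depth 12, with 97.2% of the listed cytosines at 3 or more reads. In the deposited calls no cytosine under 3 reads was called methylated. At 3 to 35 reads nearly every cytosine with at least 2 methylated reads was called (100% in CG and CHG, 99.3% in CHH), so a call depends on the depth of the cytosine.

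The methylation level of a region is the sum of methylated reads divided by the sum of all reads, over cytosines with at least 3 reads (the weighted level). H stands for A, C or T in the contexts CHG and CHH. Read counts of a region are summed over its cytosines, so a read of 150 bp counts at every cytosine it covers. Exact Clopper-Pearson 95% intervals treat these counts as independent. They cover no biological error and can be too narrow even for counting error. Reads without molecular identifiers are not independent molecules either. A second 95% interval came from 1000 resamplings of 100-kb windows and describes spread along the genome. With 1 table, of 1 or more libraries, there is no biological error, and chromosomes, genes and cytosines are not replicates.

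Genes came from a RefSeq table on assembly TAIR10.1, from which extents and types were used. Strand, exons, untranslated regions and a genome-wide set of transposable elements were not used here, and the Sadhu retrotransposons are listed in that table as pseudogenes. Its coordinates were checked against the cytosines of the file at transfer RNA genes. The conserved C and G of these genes lay at the annotated place in 540 of 625 (86.4%), and in at most 43.0% at any other shift of up to 10 bp. The share was 67.2% on chromosome 1 and 95.8% to 100% on the others. No gene coordinates from that table are printed, and positions given are those of windows in the file (TAIR10). The test of gene classes had been planned on coding sequence and ran on whole gene bodies. The planned upstream and downstream regions became 1 kb flanks on both sides. Where annotated genes overlap, a cytosine counts as a feature for the protein-coding gene first, and then for the pseudogene. As an annotated feature, flanks leave out stretches inside other annotated genes. The flanks of single genes and of gene lists keep such stretches, so they can hold bodies of neighbouring genes. Pericentromeres are the regions within 2 Mb of rounded centromere positions fixed before the data were examined.

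Protein-coding genes with at least 20 covered cytosines in each context were classed by one-sided exact binomial tests. Each test set the number of methylated cytosines by the authors' call against the mean share over all genes, which was 19.8% in CG, 1.97% in CHG and 0.470% in CHH. Benjamini-Hochberg adjustment ran per context at 0.05. Gene body methylated (gbM) genes passed in CG alone, mCHG genes passed in CHG and not in CHH, and mCHH genes passed in CHH. Genes that passed in none are called not enriched, which does not mean free of methylation. Cytosines within a gene are not independent, so the adjusted p-values rank genes within this library. Simulated data over 25875 genes gave every gene the mean shares, with independent cytosines, and raised a small set of genes in a single context. A 2-fold change over the mean recovered 77.6% of simulated gbM genes and 0% of mCHG and mCHH genes. A 4-fold change recovered 100%, 41.8% and 48.5%, and a 10-fold change 100%, 100% and 95.5%. Real genes differ widely in level and their cytosines are not independent, so these rates may not hold for them.

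Named genes follow a rule fixed before the data were examined. It comprises 8 lists with 54 genes and, for each of gbM, mCHG and mCHH, the 5 genes with a symbol and the highest level in the defining context among those with at least 100 covered cytosines of it. For each list gene the 200-bp window with the highest CHH level within the gene and its flanks was also taken. This choice was made after the file was seen. Taking the highest window favours high CHH values, which the exact intervals do not allow for. The median of each list was placed among 10000 random lists of equal size matched on gene length.

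Methylated domains were defined after the file was seen, as runs of 100-bp tiles with a CHG level of at least 20% and at least 10 CHG reads. No chloroplast or spiked control was used here to measure non-conversion. The pooled CHH level of genes that were not enriched, 0.316%, served as its upper bound, since it holds true methylation as well. Alternatives covered the coverage minimum, the averaging of cytosines, high-coverage cytosines, the width of the pericentromere, the class settings, own calls and thinned reads. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.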

Results

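The series was made around ALY1, an mRNA export factor, and the RNA-directed DNA methylation (RdDM) pathway, in which small RNAs guide cytosine methylation. The methylome described here is the table recorded for wild-type replicate 1 from immature flower buds, at a mean depth of 12.2 reads per listed cytosine. It is a wild-type reference for the mutants of ALY1, DNA methyltransferases, polymerase V and Dicer-like genes in the series. Only this 1 table was analysed, and whether it pools libraries is not given, so no value below has a replicate error.

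Methylation was highest at CG sites, lower at CHG and lowest at CHH. The nuclear genome carried 21.8% CG methylation (95% interval from resampling windows 20.7 to 23.0, 64491918 reads). The CHG level was 7.25% (6.64 to 7.88, 71836241 reads) and the CHH level 1.33% (1.26 to 1.41, 366720629 reads). CHH sites made up 72.7% of the cytosines and held 20.2% of the methylated reads, while CG sites made up 13.0% and held 58.2%. Both strands of a site were usually alike. Across 1317379 CG pairs with at least 10 reads per strand the correlation of the strands was r = 0.986 (Spearman's rho 0.878), and across 1275287 CAG/CTG pairs it was r = 0.944 (rho 0.643). These correlations are across sites, which are not independent replicates. Of 240317 CG pairs with a strand at 50% or more, 137 had the other strand under 10%.

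The comparison of pericentromeres with chromosome arms asks where heterochromatic methylation lies. All 5 chromosomes were more methylated near their centromeres in each context. The CG level was 60.1% in pericentromeres and 15.4% in arms, a difference of 44.7 percentage points (33.7 to 58.4). CHG reached 34.0% against 3.13%, a 10.9-fold ratio, and CHH 3.97% against 0.889%, a 4.47-fold ratio. Over chromosomes the pericentromeric CG level was 65.6% ± 16.3 (SD, n = 5) and that of the arms 15.6% ± 1.11 (SD, n = 5). Chromosome 2 had the lowest pericentromeric CG level, 37.2%, and held 1 segment of high depth. Without that segment its level was 75.7%, and the level over all pericentromeres was 73.4%.

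**Figure D1:**
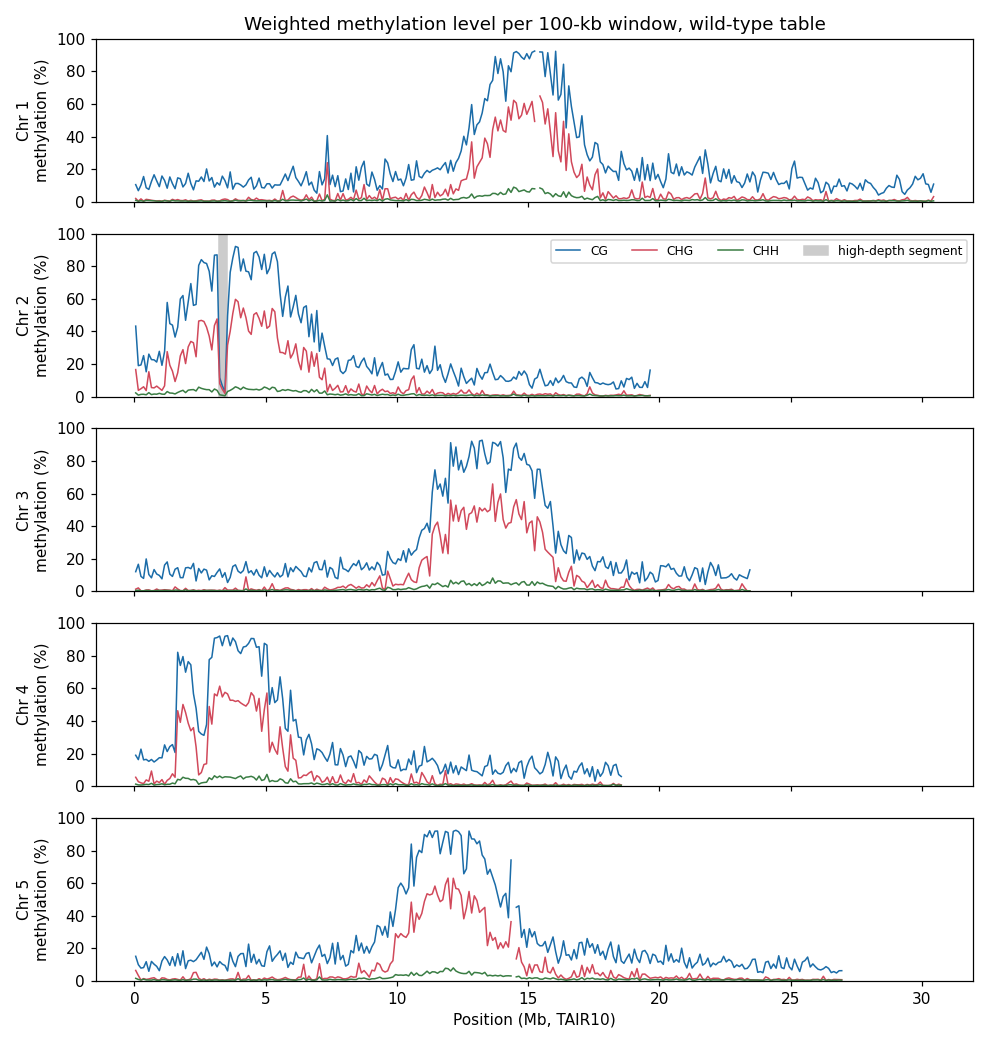
Weighted methylation level (%) per 100-kb window along the 5 chromosomes (position in Mb, TAIR10) for CG, CHG and CHH, with windows of fewer than 1000 listed cytosines left out. Levels rise around the centromeres, and the grey band on chromosome 2 marks the segment of high depth, where CG methylation was 5.38%.

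The segment spanned 270 kb within the pericentromere of chromosome 2 (3240001 to 3510000). Its mean depth was 100.5 reads per cytosine, against 11.1 in the 200-kb flanks on both sides. CG methylation in it was 5.38% (exact 95% interval 5.35 to 5.41) and 82.5% (82.4 to 82.7) in the flanks. CHG was 3.65% against 44.8% and CHH 0.678% against 4.09%. It held 2.16% of all reads over cytosines on 0.268% of the cytosines. Of its 93 protein-coding genes, 43 were classed mCHH, 35 mCHG, 1 as not enriched and 14 had too few cytosines to be classed. At such depth few methylated reads among many suffice for a call, so these classes do not show high levels.

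The comparison of annotated features asks which parts of the genome carry each kind of methylation. Protein-coding gene bodies were methylated mainly at CG, with 15.2% CG (14.8 to 15.6), 1.18% CHG (1.09 to 1.28) and 0.448% CHH (0.435 to 0.461). Their 1 kb flanks had more CHG, 5.80%, and more CHH, 1.30%. The body minus flank difference was -4.62 points (-4.89 to -4.33) in CHG. The flanks had 13.5% CG, 1.69 points (1.10 to 2.27) below the bodies, but the order of bodies and flanks in CG depends on the averaging. As means of cytosine levels the bodies had 16.6% and the flanks 16.8%. Annotated pseudogenes stood apart, at 69.4% CG, 47.1% CHG and 5.76% CHH, and held 45.4% of all methylated CHG reads. This annotated class also lists retrotransposons, and its share of transposable elements was not determined, so these levels are not those of decayed genes alone. The rest of the genome, more than 1 kb from protein-coding genes and outside other annotated genes, had 41.2% CG, 22.7% CHG and 2.92% CHH.

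Outside protein-coding genes and pseudogenes, long non-coding RNA genes had 12.0% CG and 5.41% CHG. Their CG level was 3.13 points below that of gene bodies (interval of the difference -4.54 to -1.62). Gene bodies exceeded them in CG by 0.691 points as means of cytosine levels and by 4.96 points with a minimum of 10 reads. Small RNA genes had 9.36% CG, 4.28% CHG and 1.54% CHH. This name covers transfer, micro, small nucleolar, small nuclear and ribosomal RNA genes, and the class was not chosen for the small RNAs of RdDM. After subtraction of the upper bound of non-conversion the CHH level of gene bodies was 0.132%, so most of the 0.448% cannot be told from unconverted cytosines.

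**Figure D2:**
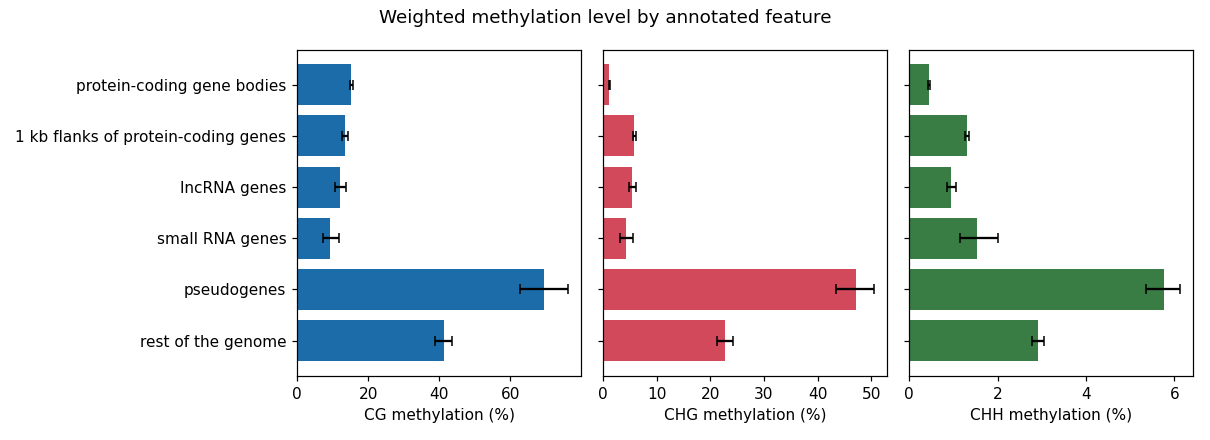
Bars show the weighted methylation level (%) of 6 annotated features in CG, CHG and CHH, each context on its own scale, in the wild-type table. Small RNA genes are transfer, micro, small nucleolar, small nuclear and ribosomal RNA genes. Error bars are 95% intervals from resampling 100-kb windows. Annotated pseudogenes, a class that also lists retrotransposons, have the highest level in each context.

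Gene classes count the protein-coding genes enriched in CG alone and those enriched in CHG or CHH, each over the mean of all genes. Of 27444 genes, 25875 could be classed. Gene body methylation was found in 4949 genes (19.1%), CHG enrichment without CHH in 280 (1.08%) and CHH enrichment in 1407 (5.44%). The other 19239 genes were not enriched in any context. Of these classes 245 mCHG and 1364 mCHH genes lay outside the chromosome 2 segment. Classing again without the genes of the segment, with the mean shares recomputed, gave 248 and 1367.

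The classes differed in length and place. The median length was 3541 bp for gbM genes, 1951 bp for genes that were not enriched, 1597 bp for mCHG and 1698 bp for mCHH genes. Pericentromeres held 29.9% of the mCHH and 27.5% of the mCHG genes, against 5.21% of the gbM and 1.88% of the not enriched genes. Among the 1364 mCHH and 245 mCHG genes outside the segment these shares were 27.6% and 17.1%. The median CG level of gbM bodies was 31.8% (interquartile range 26.1 to 39.6) with 0.395% CHG and 0.313% CHH. Genes of the mCHH class had medians of 60.7% CG, 29.9% CHG and 3.12% CHH.

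CG methylation of gbM genes was low at both gene ends and rose inward. It was 3.21% in the first 100 bp inside the gene end, 40.8% at about 950 bp and 55.6% at about 1950 bp. Bins end at a gene's midpoint, so the inner bins hold the longer genes alone. In the 1947 gbM genes of at least 4 kb, which fill every bin, the 3 levels were 1.44%, 36.7% and 55.6%. Over all mCHH genes CHG was 30.1% in the first 100 bp inside and 16.8% at about 950 bp. Most of that difference was absent from the 566 mCHH genes of at least 2 kb, with 18.4% and 16.8% CHG and with 33.7% and 35.7% CG at the same places.

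**Figure D3:**
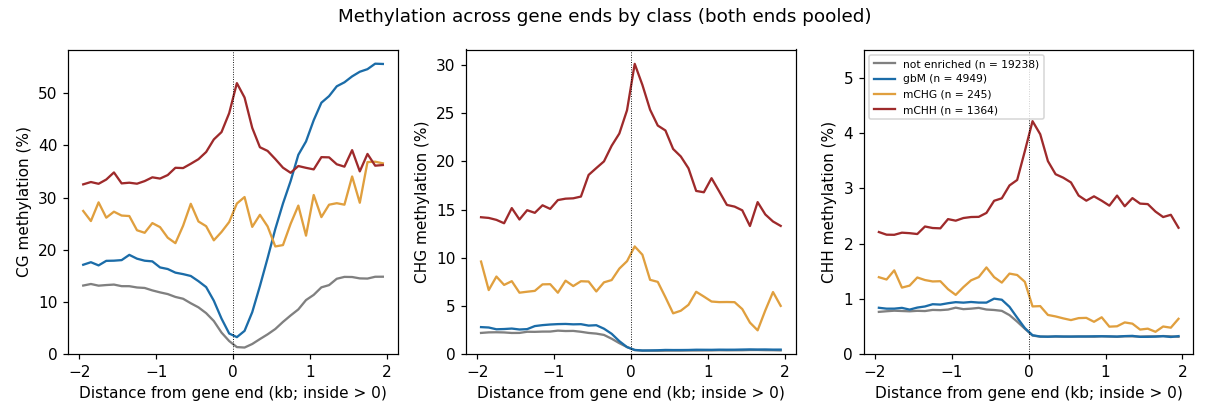
Weighted methylation level (%) in 100-bp bins across gene ends (distance in kb, positive inside the gene) for 4 gene classes, with both ends of each gene pooled, bins up to the gene's midpoint so that inner bins hold longer genes alone, and the genes of the chromosome 2 segment left out. In gbM genes CG rises from 3.21% at the end to 55.6% at about 1950 bp inside.

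Among genes with a symbol and at least 100 covered CG cytosines, the gbM genes with the highest CG level were ACC1, which encodes an acetyl-CoA carboxylase, with 68.5% (67.2 to 69.9), and SUVR5, a relative of histone methyltransferases, with 66.0%. PTM had 65.8%, the immune receptor gene TAO1 64.9% and the protease gene SLP3 64.5%. All 5 kept CHG and CHH below 0.6%. Among mCHG genes with a symbol and at least 100 covered CHG cytosines, PDLP6 had the highest level, 12.8% CHG (10.8 to 14.9), followed by the cytochrome P450 gene CYP76C6 with 10.2% and ACD32.1 with 9.65%. ZFP4 had 9.13% and the disease resistance gene RPP5 9.11%, and ZFP4 was not enriched when a minimum of 10 reads was set. Among mCHH genes under the same limit for CHH cytosines APD3 had 18.4% CHH (15.8 to 21.3) over 214 covered CHH cytosines, and the receptor kinase gene RKF2 13.9% (13.1 to 14.7) over 745. CYP79A4P had 13.4%, PUM25 12.2% and ADR1-L3, a relative of immune receptors, 12.1%, each with 84.6% CG or more. APD3, CYP79A4P and PUM25 had too few covered cytosines to be classed with a minimum of 10 reads or of 40 cytosines per context, and APD3 also with thinned reads.

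The gene lists ask how the methylation machinery and genes of known behaviour are themselves methylated. Of the 54 genes, 34 were not enriched, 14 were gbM, 4 mCHG and 2 mCHH. The class was the same in all 8 alternative settings for 47 of them. Of the 48 list medians placed among random lists, 8 lay in the outermost 5%, where chance would give about 2.40 if medians were independent. Some belong to the silencing and imprinting list, which was chosen for such methylation. Others are low levels. Body CHH of the ALY list was 0.227% (percentile 0.46), and flank CHG of the maintenance list 0.170% (percentile 0.645). Both lie below the 0.316% that bounds non-conversion. The count is therefore not read as an excess over chance.

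RdDM genes were mostly body methylated, with 7 of 10 in the gbM class. NRPD1 (AT1G63020), the largest subunit of RNA polymerase IV, had 61.7% CG (60.4 to 63.1) and DCL3 (AT3G43920), which makes the small RNAs of the pathway, 60.6% (58.8 to 62.3). RDR2 had 50.6%, DCL4 35.5%, DCL2 34.7%, NRPE1 31.3% and AGO4 29.3%. AGO6 at 13.5% and DRM1 at 0.302% were not enriched. DRM2 (AT5G14620), the methyltransferase of the pathway, was mCHG with 5.99% CHG (5.19 to 6.87). The list's median body CG of 33.0% lay at percentile 85.4 of random lists and its flank CG of 26.1% at percentile 99.4. Flanks of list genes can hold bodies of neighbouring genes, so this flank level may include gene body methylation of neighbours.

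Among the maintenance factors CMT2 and SUVH4 were gbM, with 26.1% and 39.9% CG, and MET1, CMT3, DDM1 and VIM1 were not enriched. CMT3 was classed mCHG with a minimum of 10 reads. IBM1 (AT3G07610), a histone demethylase that keeps genes free of CHG methylation, was itself mCHG. Within the gene the window from 2430201 to 2430400 on chromosome 3 had 94.0% CG, 81.5% CHG (73.8 to 87.8, 130 reads) and 3.70% CHH. The CG methyltransferase gene MET1 (AT5G49160) had 12.2% CG in its body. A window outside the gene, 19931401 to 19931600 on chromosome 5, had 27.1% CHH (23.1 to 31.5, 446 reads).

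ALY1 (AT5G59950), the gene the series is about, had 6.08% CG (4.99 to 7.33), 0.213% CHG and 0.219% CHH and was not enriched. ALY2 with 0.254% CG and ALY3 with 10.7% were not enriched either. ALY4 (AT5G37720) was gbM with 45.3% CG (42.3 to 48.3). Next to ALY4, the window 14985001 to 14985200 on chromosome 5 had 92.6% CG and 25.7% CHH (22.1 to 29.6, 537 reads).

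Of the DNA demethylase genes, DME was gbM with 27.7% CG and DML2 and DML3 were not enriched. ROS1 (AT2G36490), a demethylase whose promoter methylation is known to tune its expression, was mCHG at an adjusted p of 0.0440 (exact binomial test). It was gbM in 4 of the 8 alternative settings. Across one end of ROS1 the window 15314801 to 15315000 on chromosome 2 had 67.1% CG and 41.5% CHG (26.3 to 57.9).

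Of 8 loci known for silencing or imprinting, 2 were mCHH, 1 was mCHG and 5 were not enriched. FWA (AT4G25530), a homeobox gene silenced in vegetative tissue, and SDC (AT2G17690), an F-box gene silenced by non-CG methylation, were mCHH, with adjusted p of 0.0214 and 0.0180 (exact binomial test). In 3 of 8 settings FWA became gbM and SDC mCHG. In FWA the window 13038601 to 13038800 on chromosome 4 had 87.4% CG and 6.51% CHH. Across one end of SDC, 7682001 to 7682200 on chromosome 2 had 91.5% CG, 58.3% CHG and 13.1% CHH. QQS was mCHG with 27.0% CHG (23.3 to 30.9), and a window outside it had 93.5% CG and 73.3% CHG. It had too few cytosines to be classed in 2 settings.

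The imprinted genes MEA, FIS2 and PHE1 were not enriched in their bodies, with 0.352%, 1.11% and 1.28% CG. FIS2 was classed mCHG with a minimum of 10 reads. Windows outside these genes had 91.4%, 95.8% and 82.9% CG in the same order. SUP and FLC had 0% and 0.363% CG, and 0 of 333 reads at SUP allows up to 1.10% (upper exact 95% bound). The list's body CHG median of 1.22% lay at percentile 99.8, its body CHH of 0.411% at 98.7 and its flank CG of 27.5% at percentile 99.1. The list was chosen for known silencing or imprinting, so high percentiles are no independent result.

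All 7 floral identity genes were not enriched, with body CG between 0% in PI and 0.550% in SEP3. AG had 0.296%, AP1 0.518%, AP3 0.125%, LFY 0.236% and WUS 0.349%. The list median of 0.296% lay at percentile 0.280 of random lists. The 5 seed storage genes, which are active in seeds, were not enriched either, with 0.183% CG in OLEO1 to 0.606% in CRB. Their median of 0.314% lay at percentile 10.3, and their flank CG of 0.211% at percentile 2.34.

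Of 9 constitutively expressed reference genes, PP2AA3 with 32.6% CG, SAND with 28.1% and CACS with 24.4% were gbM. The other 6 were not enriched. Of these TIP41L had 14.2% CG and YLS8 3.46%, and ACT2, UBQ10, GAPC1 and UBC9 had under 0.5%. The window 18920001 to 18920200 on chromosome 5, outside CACS, had the highest CHH level of the list windows, 35.6% (31.8 to 39.6, 604 reads), with 86.8% CG.

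The bases beside a cytosine bear on which enzyme methylates it, since CMT2 is known to prefer CAA and CTA. Enzymes were not told apart here, because no mutant was analysed. CAA had 2.44% and CTA 2.54% methylation, against 0.850% over the other CHH trinucleotides, a ratio of 2.91 (2.81 to 3.03). The ratio was 2.01 (1.94 to 2.07) in arms and 4.96 (4.74 to 5.15) in pericentromeres. Non-conversion, with an upper bound of 0.316%, was not subtracted from these levels. The other CHH sites had 0.684% in arms and 1.83% in pericentromeres, so non-conversion can lower the ratio more in arms. Part of the contrast between arms and pericentromeres may therefore come from non-conversion. CCT was lowest, at 0.521%, a level that also includes any unconverted cytosines. Among CHG sites CCG had 4.78% and CAG and CTG 7.75% and 7.83%. CCG was at 0.733 of the other CHG sites in arms (0.711 to 0.757) and at 0.476 in pericentromeres (0.445 to 0.512).

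CHG-methylated domains numbered 15508, covered 17.8 Mb and held 89.4% of the methylated CHG reads. A genome-wide annotation of transposable elements was not used here. The 6817 domains under 0.5 kb had 11.5% methylation at CAA and CTA and 6.62% at other CHH sites, a ratio of 1.74 (1.68 to 1.81). The 950 domains over 4 kb had 20.3% and 3.33%, a ratio of 6.09 (6.01 to 6.17). The ratio rose by 4.35 (4.26 to 4.44) from short to long domains, and by 4.09 (3.98 to 4.22) within arms alone. The total CHH level was 8.23% (7.89 to 8.57) in the short and 8.01% (7.80 to 8.24) in the long domains, a difference whose interval of -0.0787 to 0.559 points includes 0. Within pericentromeres the short domains had 5.06% (4.79 to 5.32) and the long ones 7.25% (7.08 to 7.42), a difference of -2.20 points (-2.45 to -1.95). Within arms they had 10.5% and 10.8%, and the interval of the difference, -0.803 to 0.263 points, includes 0. Arms held 59.6% of the short and 22.3% of the long domains.

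**Figure D4:**
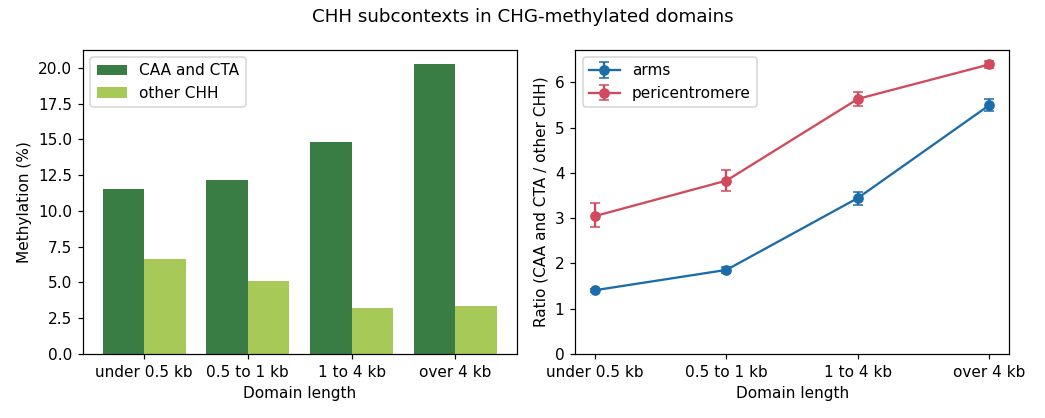
The bars give the methylation level (%) of CAA and CTA and of other CHH sites in CHG-methylated domains of 4 length classes, and the points give their ratio in arms and pericentromeres with 95% intervals from resampling windows. Over all domains the ratio was 1.74 under 0.5 kb and 6.09 over 4 kb.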

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

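The alternatives without the segment, with the bound subtracted, with own calls (thinned reads included), for gene ends by gene length and for domains were chosen after the data were seen, and the others before. Not run were a chloroplast background, coding sequence alone, a genome-wide set of transposable elements and thinning with the authors' calls, for want of these in what was used here. The order CG, CHG, CHH, the excess of pericentromeres over arms and the class counts within 1.5 times held in every setting run. Values are given in the order CG, CHG and CHH. Genome levels were 22.0%, 7.35% and 1.34% with a minimum of 1 read, and 18.2%, 5.31% and 1.11% with 10 reads. They were 26.6%, 9.68% and 1.62% as means of cytosine levels, and 22.3%, 7.29% and 1.33% without cytosines above the percentile of 99 in coverage. They were 22.3%, 7.35% and 1.35% without the segment, and 21.6%, 6.96% and 1.02% after subtraction of the bound. The pericentromere minus arm difference was 45.0, 31.1 and 3.11 points with 1 read, 36.5, 24.9 and 2.53 with 10 reads and 58.8, 40.04 and 3.90 as means. It was 58.2, 38.0 and 3.62 without high coverage, 58.0, 37.9 and 3.61 without the segment, and 44.9, 31.0 and 3.10 after subtraction. Within 1 Mb it was 37.5, 29.3 and 2.84, and within 3 Mb 38.8, 25.2 and 2.64. Gene bodies had 15.2%, 1.19% and 0.449% with 1 read, 14.1%, 0.975% and 0.423% with 10 reads, and 16.6%, 1.40% and 0.473% as means. They had 15.4%, 1.13% and 0.442% without high coverage, 15.4%, 1.14% and 0.445% without the segment, and 14.9%, 0.864% and 0.132% after subtraction. Gene bodies minus their flanks gave 1.64, -4.65 and -0.860 points with 1 read, 2.502, -3.88 and -0.726 with 10 reads, 1.62, -4.78 and -0.883 without high coverage, and 1.66, -4.72 and -0.871 without the segment. As means they gave -0.147, -6.07 and -1.10 points, so the order in CG turned, and the cause was not tested. CCG was 3.42% with 10 reads and 2.40% in arms. With 5 reads per strand r was 0.982 for CG and 0.937 for CAG/CTG. The CHH difference of short minus long domains was 0.677 points at 8 to 15 reads, 0.888 at a CHG minimum of 10%, -0.823 at 30%, -0.255 in arms and -2.20 in pericentromeres. The ratio difference was 4.55 at 8 to 15 reads, 4.49 at 10%, 3.94 at 30% and 4.09 in arms. Outside the domains the cause was not tested. Class counts ranged from 4435 to 4977 for gbM, 211 to 327 for mCHG and 969 to 1593 for mCHH. Of 176 other values 43 stayed within their error and 133 moved beyond it. The CHG excess of the first 100 bp of mCHH genes over about 950 bp inside fell from 13.3 points to 1.62 in genes of at least 2 kb and 1.09 in genes of at least 4 kb, since inner bins hold longer genes alone. With 0.5 of the reads and own calls, 97.1% of 25570 genes had the same class as with own calls at full depth, and 1047 mCHH genes remained of 1332. The count of mCHH genes went from 1332 to 1066, that of gbM from 4969 to 4824 and that of mCHG from 298 to 309. Genes that kept their class were counted for mCHH alone, and some genes could no longer be classed. CG sites with 3 to 9 reads were at 39.1% and those with 10 to 25 reads at 18.5%, and within gbM bodies at 42.9% and 33.2%, so the coverage minimum shifts levels.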

Other observations

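The tests on the chromosome 2 segment and the values of domains within pericentromeres, or within arms at 8 to 15 reads, were chosen after the results had been seen. The other tests on domains, that within arms included, and that on gene length were chosen before their results were seen.

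High CHG methylation continued past the bounds of the pericentromeres set here. Of 993 arm windows of 100 kb, 37 had over 20% CHG, against a median of 1.61%. Of these 34 lay within 3 Mb of the centromere, next to the bound of 2 Mb. Of the 3 others, 2 were on chromosome 2 (6700001 to 6800000 and 6900001 to 7000000) with 27.4% and 26.4% CHG. The third, 7300001 to 7400000 on chromosome 1, had 40.6% CG and lay 7.65 Mb from the centromere. The highest level was at 1800001 to 1900000 on the short arm of chromosome 4, with 79.5% CG, 50.1% CHG and 5.46% CHH. Its neighbours from 1600001 to 1700000 and from 1700001 to 1800000 had 46.3% and 39.2% CHG. The short arm of chromosome 4 in Columbia is known to carry a heterochromatic knob.

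Of 3959 annotated pseudogenes tested against the gene means, 3315 (83.7%) were mCHH and 527 were not enriched. That annotated class also holds retrotransposons, the Sadhu elements among them. Of 3480 long non-coding RNA genes, only 1100 had enough covered cytosines to be tested. Among those tested, 826 (75.1%) were not enriched, 130 were gbM and 123 mCHH. Both types were tested over their whole extent, so cytosines of overlapping protein-coding genes can enter these counts. The 16 Sadhu elements, non-autonomous retrotransposons, ranged from 0% to 96.5% CG. In 8 of them CHG was over 10%, with SADHU6-1 highest at 75.6% CHG and 96.5% CG. SADHU5-1 lay between, with 10.6% CG and 3.03% CHG, while SADHU10-1 had 0.103% CG and SADHU4-1 had 0% CG. The Sadhu elements were singled out after the file was seen. The outer 200 bp of 2285 domains over 2 kb had 6.57% CHH against 7.61% inside. CG and CHG were lower there too, at 91.4% against 92.2% and 54.7% against 62.2%. Domains end where tiles fall below the CHG minimum, so lower edges can follow from the definition and are no separate result on CHH.

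The segment of chromosome 2 combined low methylation with high depth. The longest run of 10-kb windows under 20% CG there, picked without regard to depth, was the same 270 kb. Since the segment had been found by its depth, this run repeats its depth and is no independent test. The depth itself, 9.02 times that of the flanks, argues against an unmethylated single-copy nuclear segment. Reads of unmethylated organelle DNA placed on a nuclear copy may account for it, since this chromosome is known to carry a large insertion of mitochondrial DNA near its centromere. Reads added to a copy as methylated as the flanks would leave about as many methylated reads per CG site, and the segment had 0.628 of those of the flanks (0.334 to 0.954 over its pieces), so this stays open. Many unmethylated nuclear copies collapsed into 1 cannot be told apart from organelle reads, because both give a depth such as the 8.26 times the genome mean seen here. No biological explanation was tested.

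The CHH level of all domains differed between short and long ones by 0.224 points, within its interval, whereas within pericentromeres the difference ran from -1.60 to -2.69 points across the main setting, 8 to 15 reads and CHG minimums of 10% and 30%. The CHG minimum may set the sign of the pooled value, which was 0.888 points (0.580 to 1.21) at 10% and -0.823 (-1.14 to -0.473) at 30%. Position along the chromosome enters the pooled value. Arms had more CHH methylation in short and in long domains, and held 59.6% of the short and 22.3% of the long ones. The pooled value thus stands for neither region. Within arms the difference was -0.255 points (0.315 at 8 to 15 reads). Within pericentromeres it was -2.20, and -2.04 (-2.32 to -1.75) at 8 to 15 reads. Read depth stays open as a cause of the pooled value. The rule set beforehand against depth asked that the difference persist at 8 to 15 reads with an interval that excludes 0. The 0.677 points (0.318 to 1.05) there met it. They were set against a pooled difference whose own interval includes 0, so the rule cannot decide. Different CHH methylation pathways at short and long domains are a hypothesis consistent with the ratio of CAA and CTA to other CHH sites, which was higher by 4.35 in long domains. The cmt2 and polymerase V mutants bear on it directly and were not analysed here.

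The share of gbM genes rose with gene length, from 2.97% of the 6469 shortest genes to 47.9% of the 6467 longest. A greater power of the test in long genes was weighed as the whole cause. With 20 cytosines drawn per gene and context the share was 2.35% in the shortest genes and 10.2 times as high in the longest. The cutoff set beforehand for power as the whole cause was a ratio of at most 1.5. The ratio with all cytosines was 16.1, so part of the trend may come from power. No biological explanation was tested.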
